A study of Mus musculus with 6 samples.

How the data were processed

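The submitters' notes name FastQC 0.11.2, Bowtie and the mouse genome build mm10. The values are FPKM as deposited by the authors, fragments scaled by gene length and by library before deposit. The quantifier, the annotation and the strand setting are not given in the sources used here. RNA of colonic lamina propria cells was sequenced in 3 libraries of vehicle and 3 of atorvastatin. The values carry 2 decimals, and fragment counts could not be recovered from them. Gene symbols, positions and transcript lengths came from GENCODE mouse release 21, which has the same start and end for 51957 of the gene IDs; 260 IDs had no symbol.

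The design fixed at the outset put a count-based test first and limma on log2 values as the fallback for normalised values. Because the files hold FPKM, the fallback was used, and tests that need counts were not run. Genes with at least 1 FPKM in at least 3 libraries were kept (13590). Differences are of log2(FPKM + 1), which understates changes of genes with low values, and were tested with limma 3.58.1 (limma-trend, R 4.3.3) at a Benjamini-Hochberg false discovery rate of 0.05. The 39 gene lists were tested with camera on the same values with a preset correlation of 0.01, for lists with at least 5 measured members, and adjusted over lists. They were tested again with the correlation estimated from the libraries and with fry. Of 518 listed genes 517 were matched. The genes to be named were fixed by rule: the 10 smallest p, the 2 most abundant members of each list, and 19 set genes. Single values below the filter were compared by an exact permutation test. The trend on transcript length was removed per library; that setting, the same with GC content, equal sums per library, median-of-ratios scaling, robust variance, array weights, protein-coding genes alone and the ribosomal list without Rps6k kinases were chosen after the data were seen. Other values of the pseudocount and the filter, rescaling without abundant gene classes, the replicate number as a block, and leaving out single libraries had been fixed beforehand. Power was tested on simulated data made from these libraries, with 200 changed genes in each of 5 runs.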

Results

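RNA was sequenced in bulk from cells of the colonic lamina propria, the layer of connective tissue beneath the epithelium that holds most immune cells of the gut wall. The donors were male Apc Min/+ mice aged 5 to 6 weeks, which carry a truncating mutation in a single copy of Apc, a suppressor of Wnt signalling, and form intestinal adenomas. Mice of 3 libraries had received the vehicle, 2% Tween 80, by gavage, and mice of the other 3 libraries atorvastatin at 20 mg/kg on alternate days. Atorvastatin lowers cholesterol synthesis. Values were FPKM in each library, with sums between 355787 and 456064 and between 13303 and 13703 genes at 1 FPKM or more. The number of fragments behind the values is unknown. The labels do not say that the libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

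Pearson's r of log2(FPKM + 1) across genes was 0.957 on average within groups (0.939 to 0.970) and 0.956 between groups (0.938 to 0.965). Vehicle library 3 stood apart from the other 5, with a mean r of 0.944 to them against 0.957 to 0.961 for the others, and it alone lay far out on the first principal component, which held 33.5% of the variance. On the second component, with 20.5%, the groups did not overlap: the vehicle libraries lay at 14.8, 16.5 and 7.9 and the atorvastatin libraries at -27.4, 5.8 and -17.7. Immunoglobulin genes made up 34.8% ± 4.08 (SD, n = 3) of the summed FPKM with vehicle and 35.3% ± 10.9 (SD, n = 3) with atorvastatin.

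The design holds a single comparison, atorvastatin against vehicle, in a series whose title links statins, tryptophan catabolites made by the microbiota and prevention of colorectal cancer. With atorvastatin, genes of B cells and of MHC class II antigen presentation were lower as groups in limma's camera test, and so were genes for ribosomal proteins, a list included as a quality check. All 3 lists had an adjusted p = 0.699 with an estimated correlation, and no single gene passed the test over all genes. The 14 measured B cell markers were all lower, with a mean difference of -0.41 on the log2(FPKM + 1) scale (SE 0.11, n = 3 per group), and the 11 measured MHC class II genes were all lower, with a mean difference of -0.38 (SE 0.07, n = 3 per group). Genes of Th17 cells and of the IL-17 response, target genes of the aryl hydrocarbon receptor, which senses tryptophan catabolites, and genes of cholesterol synthesis did not differ as groups. Of 39 gene lists fixed before the data were examined, 36 had at least 5 measured members, and 10 passed limma's camera test at a false discovery rate of 0.05, 3 of them higher and 7 lower with atorvastatin. With an inter-gene correlation estimated from the 6 libraries 0 lists passed in camera, where 1 had an unadjusted p under 0.05, and in fry, limma's rotation test, 0 passed and 5 had an unadjusted p under 0.05.

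The test of single genes was limma on log2(FPKM + 1), and 0 of 13590 genes passed a false discovery rate of 0.05 or of 0.1. At an unadjusted p under 0.05 there were 974 genes, 425 higher and 549 lower, against 680 by chance. The groups did not overlap in 1955 genes, 14.4% of those tested, where chance gives 10%. The 95% interval of the difference lay within 1 log2 unit of 0 for 12205 genes (89.8%). The log2(FPKM + 1) scale understates changes at low FPKM. There an interval within 1 unit does not exclude a 2-fold change. In data simulated from these libraries a 1.5-fold change was called in 4.8% of 250 altered genes. A 2-fold change was called in 44.4% and a 4-fold change in 78%. Each run mixed these with 8-fold changes and drew genes independently. Larger changes ease the threshold for smaller ones, so 2-fold changes alone may be called less often. No list member passed over all genes, so the counts given below of members past the threshold are adjusted over the list alone.

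B cell markers had an adjusted p of 1.96e-08 in camera, and an adjusted p = 0.699 with an estimated correlation. Of the 14 markers, 7 were lower when adjusted over the list alone and 0 over all genes. Cd79a (ENSMUSG00000003379, chromosome 7, 24897381 to 24902197), a signalling chain of the B cell receptor, had 180 ± 26.1 FPKM (SD, n = 3) with vehicle and 127 ± 9.16 (SD, n = 3) with atorvastatin, and its partner Cd79b had 81.7 ± 16.3 and 61.2 ± 8.82 FPKM. Cd79a passed the threshold in the list and Cd79b did not. Members besides Cd79a that passed it, named after their values were seen, included Ms4a1, which encodes CD20 (17.8 ± 1.55 and 11.3 ± 2.77 FPKM), Fcrla, Bank1, Cd72 and Fcer2a, with log2 differences from -0.71 in Fcrla to -0.40 in Fcer2a. The mean level of the list was lower in each atorvastatin library than in every vehicle library, for which the exact permutation test gives p = 0.1, the smallest that 3 against 3 libraries allow. MHC class II genes had an adjusted p of 4.68e-07 in camera, and an adjusted p = 0.699 with an estimated correlation. Cd74, the invariant chain, had 1826 ± 266 FPKM with vehicle and 1491 ± 69.3 with atorvastatin, and H2-Ab1, a beta chain of the class II dimer, had 401 ± 46.6 and 312 ± 11.7 FPKM. Adjusted over the list alone, 3 of the 11 genes were lower, and all of them, named after their values were seen, encode chains of H2-DM, which loads peptides, or of H2-O, which restrains it: H2-Oa (-0.59, SE 0.13), H2-Ob (-0.58, SE 0.17) and H2-DMb2 (-0.59, SE 0.17). Both lists stayed past camera's threshold when any single library was left out.

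Plasma cell markers had a mean difference of -0.08 and a camera adjusted p of 0.99: Jchain, the joining chain of secreted IgA and IgM, had 2561 ± 1039 FPKM (SD, n = 3) with vehicle and 2773 ± 1178 with atorvastatin, Igha 18800 ± 2620 and 19030 ± 8485, and Igkc 55030 ± 2215 and 54020 ± 22910. Germinal centre B cell markers, with Fas and Neil1 the most abundant, had a mean difference of 0.10 (camera adjusted p = 0.271). T cell markers had a mean difference of -0.05 (camera adjusted p = 0.579), and Cd3e, a chain of the T cell receptor complex, had 4.86 ± 1.57 and 4.51 ± 1.01 FPKM. Their most abundant members were Cd2 (32.4 ± 2.35 and 26.7 ± 6.46 FPKM) and Thy1 (27.5 ± 0.679 and 23.2 ± 1.57 FPKM). Immunoglobulin variable segments, led by Ighv1-81 and Igkv1-110, had a mean difference of 0.13 over 196 segments (camera adjusted p = 0.498), which turned to -0.16 and passed without atorvastatin library 2 (adjusted p = 0.0455). In the other direction it passed without atorvastatin library 1 (0.25, adjusted p = 0.0291) or 3 (0.28, adjusted p = 5.66e-03). T cell receptor segments, led by Trbv13-2 and Trbv16, had one of -0.10 over 19 segments (camera adjusted p = 0.473), which passed without vehicle library 3 (-0.28, adjusted p = 0.0238) or atorvastatin library 2 (-0.24, adjusted p = 0.022) and was 0.06 with equal sums per library. Without atorvastatin library 2 the plasma cell (-0.31, adjusted p = 1.25e-03) and T cell lists (-0.15, adjusted p = 0.02) passed too. Sequence-similar segments can share reads, and the counting behind the values is not given in the sources used here.

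**Figure D1:**
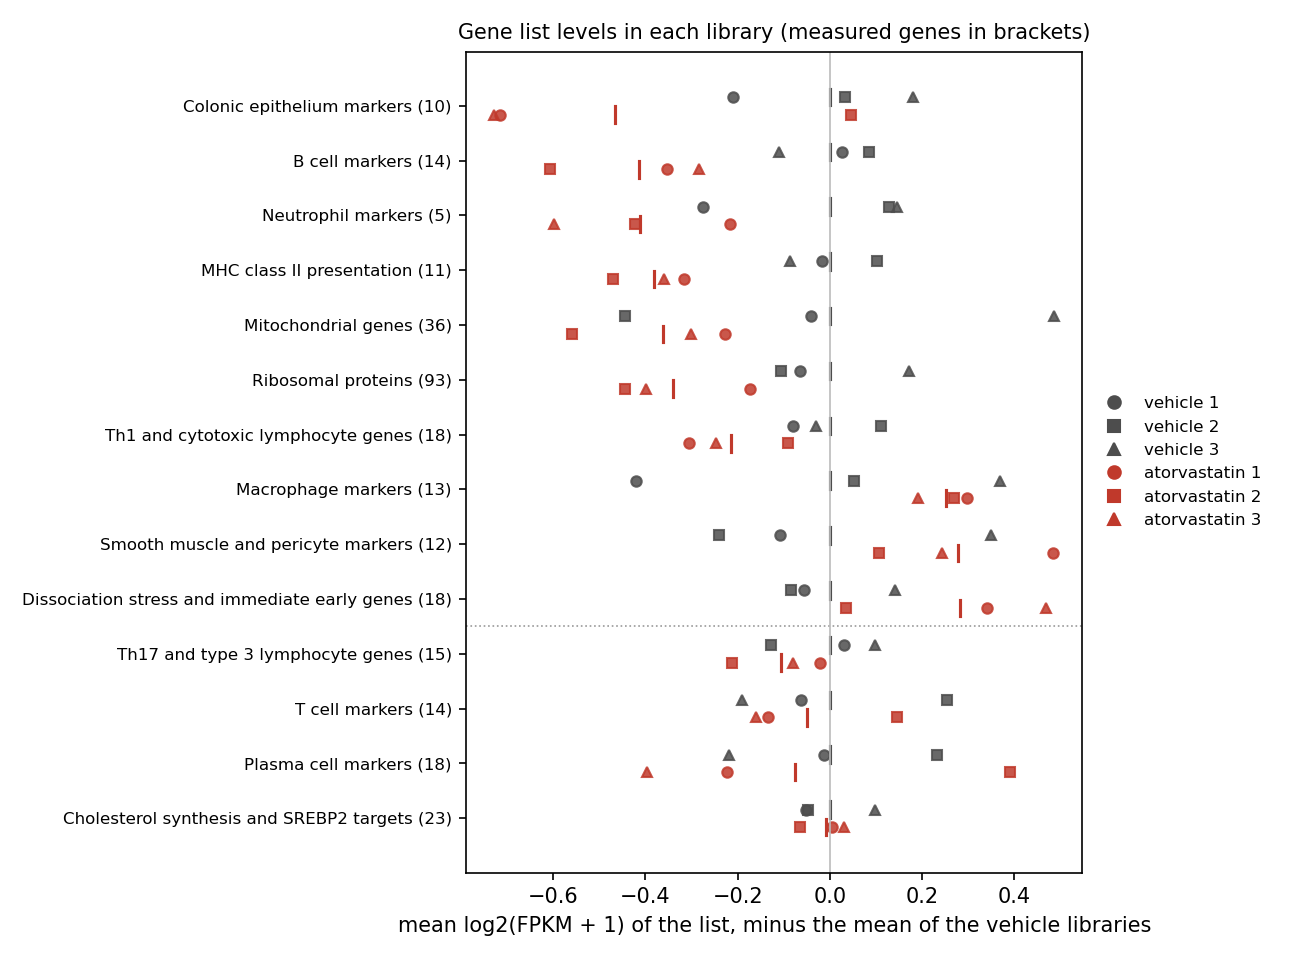
Mean log2(FPKM + 1) of each gene list in each library, relative to the mean of the vehicle libraries, for the 10 lists past camera's threshold (above the dotted line) and 4 others. Each symbol is a library, vertical bars are group means (n = 3), and the atorvastatin libraries lie below all vehicle libraries for B cell markers, MHC class II, ribosomal protein and Th1 genes.

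Th17 and type 3 lymphocyte genes had a mean difference of -0.11 (15 measured; camera adjusted p = 0.582). Il23r, a receptor chain for IL-23, had 0.870 ± 0.120 FPKM (SD, n = 3) with vehicle and 1.08 ± 0.115 with atorvastatin. Il17a had 1.03, 0.80 and 0.95 FPKM in the vehicle libraries and 0.64, 0.69 and 0.41 in the atorvastatin libraries, a separation for which the exact permutation test gives p = 0.1, the smallest that it can give here. Il17f had 1.88 ± 0.744 and 1.87 ± 0.241 FPKM, and Il22 58.3 ± 26.4 and 33.6 ± 12.1 FPKM with a log2 difference of -0.73 (SE 0.39, limma adjusted p = 0.699). Among the most abundant members, Stat3 had 78.0 ± 8.54 and 79.3 ± 7.77 FPKM and Tmem176b 81.0 ± 17.7 and 69.0 ± 6.53 FPKM. Adjusted over the list alone, 1 gene was lower: Csf2, named after its value was seen, which encodes the cytokine GM-CSF, had 35.3 ± 3.00 and 21.4 ± 1.94 FPKM, with a log2 difference of -0.70 (SE 0.12, adjusted p = 0.0133 in the list and 0.627 over all genes in limma). Genes downstream of the IL-17 receptor had a mean difference of 0.04 (camera adjusted p = 0.864) and 0 members past the threshold in the list, with 2 at an unadjusted p under 0.05 in limma. The neutrophil chemokine Cxcl1 had 399 ± 194 and 411 ± 102 FPKM, and Ccl7 had 238 ± 112 and 199 ± 59.8 FPKM.

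Target genes of the aryl hydrocarbon receptor had a mean difference of 0.03 (camera adjusted p = 0.983). The receptor gene Ahr had 8.93 ± 0.649 FPKM (SD, n = 3) with vehicle and 9.26 ± 0.722 with atorvastatin, and Cyp1a1, its best known target, had 5.07 ± 0.581 and 4.53 ± 0.544 FPKM. Tiparp had 65.8 ± 21.8 and 74.4 ± 13.8 FPKM, and Nqo1 had 9.21 ± 1.07 and 7.54 ± 0.961 FPKM. Cholesterol synthesis genes and other targets of SREBP2, the transcription factor activated when sterols are low, had a mean difference of -0.01 over 23 genes (camera adjusted p = 0.955). Hmgcs1 (0.07, SE 0.14), Sqle (0.21, SE 0.11), Insig1 (0.21, SE 0.15) and Srebf2 (0.25, SE 0.19) had positive log2 differences, and 13 of the 23 had negative ones. Fatty acid synthesis genes had a mean difference of 0.00 (camera adjusted p = 0.983), with 1 member lower adjusted over the list alone. That gene was Scd1, a stearoyl-CoA desaturase, with 35.1 ± 2.54 and 23.5 ± 1.71 FPKM (limma adjusted p = 0.0281 in the list and 0.692 over all genes), while Elovl5 had 28.4 ± 2.81 and 24.5 ± 1.35 FPKM. Targets of the oxysterol receptor LXR had a mean difference of 0.05 (camera adjusted p = 0.641), with Apoe at 65.4 ± 12.5 and 89.1 ± 18.4 FPKM and Pltp at 33.2 ± 4.80 and 36.6 ± 6.16 FPKM.

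**Figure D2:**
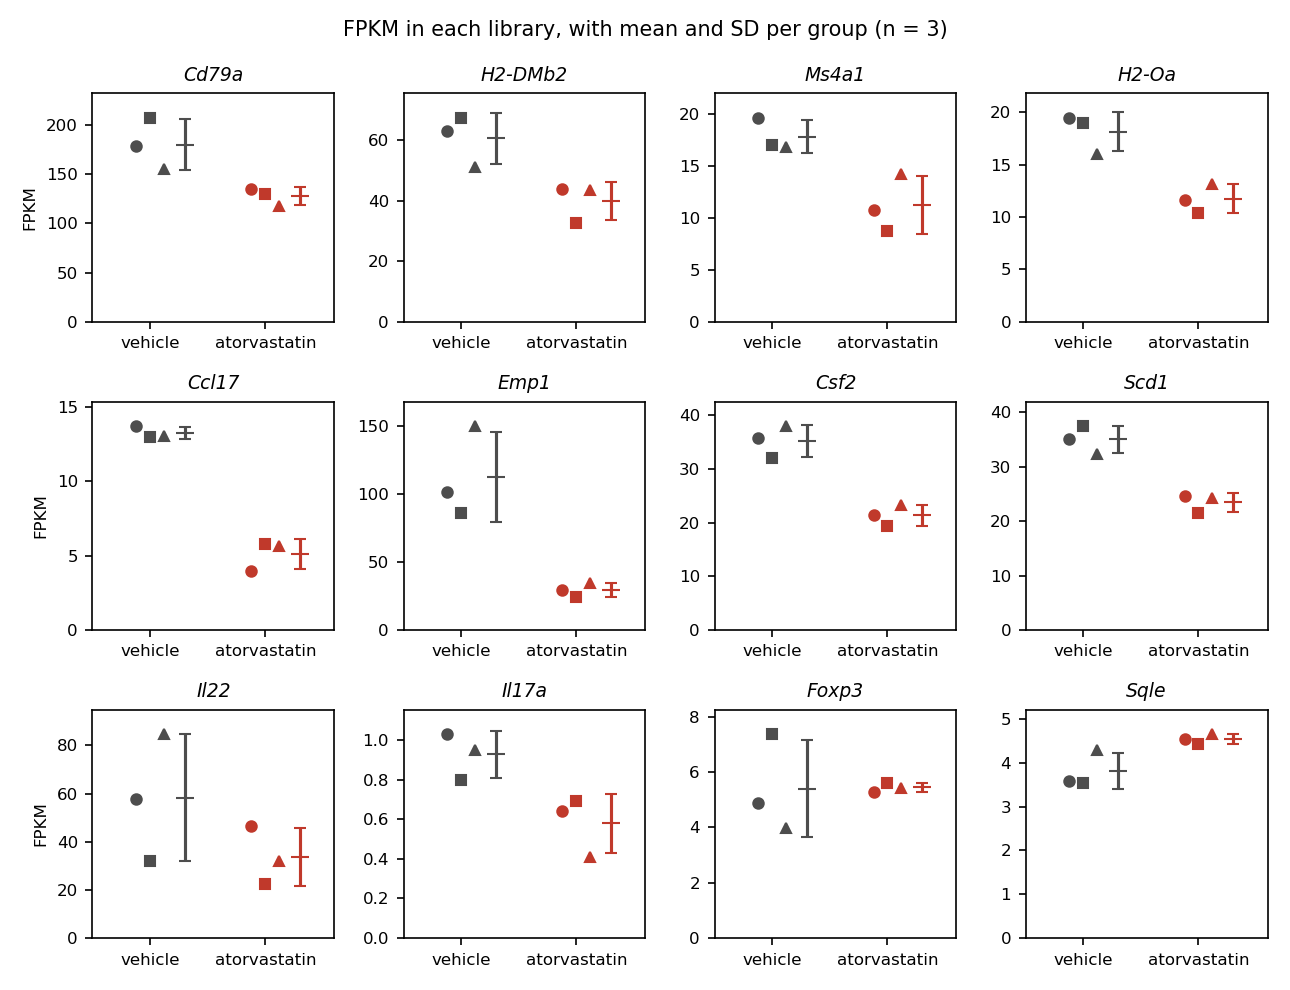
FPKM of 12 genes in each library, with the mean and SD of each group (n = 3) beside the points; each axis starts at 0. Groups do not overlap for Cd79a, H2-DMb2, Ms4a1, H2-Oa, Ccl17, Emp1, Csf2, Scd1, Il17a and Sqle, and they overlap for Il22 and Foxp3; no gene passed the limma test over all genes.

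Th1 and cytotoxic lymphocyte genes were lower as a list, with a mean difference of -0.21 (SE 0.09, n = 3 per group) over 18 genes, 16 of them lower. The camera adjusted p was 2.62e-03, with an adjusted p = 0.699 with an estimated correlation. Without vehicle library 2 the camera adjusted p was 0.0519, with a mean difference of -0.16. After a trend on transcript length was removed it was 0.0734, with a mean difference of -0.12 (SE 0.115). With a GC trend removed as well the mean difference was -0.09. The chemokine Ccl5 had 111 ± 13.4 FPKM (SD, n = 3) with vehicle and 94.0 ± 11.3 with atorvastatin, the protease Gzmb had 75.5 ± 6.28 and 69.2 ± 3.13, and Ifng had 13.3 ± 6.76 and 8.93 ± 4.35 FPKM. Adjusted over the list alone 0 genes passed, with 3 at an unadjusted p under 0.05 in limma. Genes induced by interferon gamma had a mean difference of -0.06 (camera adjusted p = 0.566; Cxcl10 566 ± 196 and 535 ± 139 FPKM, Gbp2 293 ± 49.0 and 280 ± 30.0 FPKM). Type I interferon genes had one of -0.10 (camera adjusted p = 0.215; Ifit3 489 ± 77.4 and 394 ± 103 FPKM, Isg15 452 ± 90.7 and 413 ± 89.4 FPKM). That list passed with no filter on low values (adjusted p = 0.0369) and without vehicle library 2 (-0.18, adjusted p = 0.0331) or atorvastatin library 1 (-0.18, adjusted p = 0.0235). Regulatory T cell genes had a mean difference of -0.01 (camera adjusted p = 0.983). Foxp3, which encodes their defining transcription factor, had 5.41 ± 1.77 and 5.45 ± 0.165 FPKM, Il10 39.0 ± 9.25 and 38.8 ± 7.59, and Lrrc32 31.2 ± 2.35 and 37.1 ± 7.82. Type 2 lymphocyte genes, with Il5 and Calca the most abundant, had a mean difference of -0.13 (camera adjusted p = 0.438), and NK and innate lymphoid cell markers, with Id2 and Il2rb the most abundant, one of -0.08 (camera adjusted p = 0.61). The median, the mean and the direction of the camera test differed in sign for the regulatory T cell, cholesterol synthesis and plasma cell lists, whose medians were 0.00, -0.03 and 0.00.

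Myeloid lists went in opposite directions. The 13 macrophage markers were all higher, with a mean difference of 0.25 (SE 0.23, camera adjusted p = 2.12e-03, adjusted p = 0.699 with an estimated correlation). This rested on vehicle library 1, which had the lowest level of the list: without it the mean difference was 0.04 (camera adjusted p = 0.661), and without vehicle library 3 it was 0.44. Adgre1, which encodes F4/80, had 2.45, 5.33 and 6.26 FPKM in the vehicle libraries and 5.19, 5.69 and 5.21 in the atorvastatin libraries, and lysozyme gene Lyz2 had 97.1 ± 38.4 and 113 ± 6.04 FPKM (SD, n = 3). Neutrophil markers, 5 measured, were all lower, with a mean difference of -0.41 (SE 0.18, camera adjusted p = 8.23e-03, adjusted p = 0.699 with an estimated correlation). Adjusted over the list alone, 2 were lower: S100a8 (1.40 ± 0.324 and 0.527 ± 0.310 FPKM) and, named after its value was seen, S100a9 (4.04 ± 1.01 and 1.85 ± 0.805 FPKM), which encode the subunits of calprotectin. The most abundant neutrophil markers, Il1r2 (17.5 ± 1.96 and 13.5 ± 1.47 FPKM) and Retnlg (5.67 ± 4.62 and 4.10 ± 2.11 FPKM), did not pass in the list. S100a8 reached 1 FPKM in the vehicle libraries alone, so the filter kept it only for its vehicle values. Such a choice favours a lower value with atorvastatin, and the call of S100a8 is weak support for the list. The mean difference of the list was -0.26 (SE 0.14) with the length trend removed and -0.24 with no filter on low values. Without any one vehicle library the list had fewer than 5 measured members and was not tested. Monocyte markers (mean difference -0.05, camera adjusted p = 0.955) held members on both sides, with Fn1 at 67.3 ± 6.04 and 92.9 ± 17.3 FPKM and Plac8 at 139 ± 18.9 and 104 ± 12.8 FPKM. Dendritic cell markers had a mean difference of -0.13 (camera adjusted p = 0.294; Ccr7 154 ± 27.3 and 122 ± 9.83 FPKM, Fscn1 18.2 ± 0.552 and 17.3 ± 2.42 FPKM). Mast cell markers, with Mcpt1 and Gata2 the most abundant, had one of -0.12 (camera adjusted p = 0.566), which passed without vehicle library 3 (-0.34, adjusted p = 0.0238).

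Markers of cells outside the immune compartment were also measured. Smooth muscle and pericyte markers were all higher, 12 of 12, with a mean difference of 0.28 (SE 0.21, camera adjusted p = 3.84e-04, adjusted p = 0.699 with an estimated correlation), and the call was lost without vehicle library 2 (0.16, adjusted p = 0.0894). The difference was 0.18 without atorvastatin library 1 and 0.45 without vehicle library 3. Acta2, smooth muscle actin, had 233 ± 78.7 FPKM (SD, n = 3) with vehicle and 247 ± 31.1 with atorvastatin, and Tagln had 179 ± 83.5 and 186 ± 37.9. Colonic epithelium markers were lower, 10 of 10, with a mean difference of -0.47 (SE 0.28, camera adjusted p = 8.22e-03, adjusted p = 0.699 with an estimated correlation). Leaving out vehicle library 3, atorvastatin library 1 or atorvastatin library 3 ended that call (-0.38, -0.34 and -0.28; adjusted p = 0.127, 0.148 and 0.157), and without atorvastatin library 2 the difference was -0.74. Epcam, an adhesion molecule of epithelial cells, had 12.4 ± 1.17 and 10.7 ± 2.69 FPKM, and Krt8 had 9.36 ± 2.97 and 6.03 ± 4.75. Fibroblast (0.09, adjusted p = 0.438; Dcn, Dpt), endothelial (0.06, adjusted p = 0.438; Lyve1, Plvap), glial and neuronal (-0.05, adjusted p = 0.762; Tubb3, Stmn2) and erythroid markers (-0.12, adjusted p = 0.762; Hbb-bs, Hba-a2) did not pass camera's threshold. The fibroblast list passed without vehicle library 3 (0.18, adjusted p = 0.0445) or atorvastatin library 2 (0.23, adjusted p = 0.0158), and the endothelial list without atorvastatin library 2 (0.16, adjusted p = 0.0283). Wnt and APC-responsive genes had a mean difference of 0.14 (camera adjusted p = 0.0784; Myc 62.6 ± 14.6 and 54.7 ± 11.2 FPKM, Cd44 53.7 ± 11.1 and 58.9 ± 7.21 FPKM), which passed without vehicle library 2 (0.18, adjusted p = 0.0429). Cell cycle genes had one of -0.01 (camera adjusted p = 0.983; Pcna 61.7 ± 9.64 and 59.0 ± 4.58 FPKM, Mcm4 20.3 ± 0.874 and 19.7 ± 1.56 FPKM). Eosinophil (Prg2, Il5ra), goblet (Spink4, Agr2) and adipocyte markers (Lpl, Fabp4) had 3, 3 and 2 measured members, too few to test, and mean differences of -0.02, -0.24 and 0.14.

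Lists included as checks on RNA quality and cell handling passed camera's threshold as well. Ribosomal protein genes had a mean difference of -0.34 (SE 0.12, n = 3 per group) over 93 genes, 88 of them lower, with a camera adjusted p of 7.64e-18 and an adjusted p = 0.699 with an estimated correlation. Rps3a1 had 1049 ± 131 FPKM (SD, n = 3) with vehicle and 816 ± 105 with atorvastatin, and Rps15 had 961 ± 55.5 and 818 ± 123. The list took in Rps6k kinase genes by its symbol rule, and without these the mean difference was -0.38. Removing a trend on transcript length brought it to -0.18. Mitochondrial genes had a mean difference of -0.36 (SE 0.29, camera adjusted p = 1.37e-05, adjusted p = 0.956 with an estimated correlation), which rested on vehicle library 3: without it the difference was -0.14 (adjusted p = 0.127), without vehicle library 2 it was -0.58, and with the length trend removed it was -0.03. The 36 measured mitochondrial genes had a median length of 71 nt, and the trend was fitted on protein-coding genes alone. The value of -0.03 therefore does not show that length explains the mitochondrial difference. The most abundant members, mt-Co1 and mt-Co2, had 4308 ± 823 and 3497 ± 108 FPKM, and 2368 ± 857 and 1696 ± 95.6 FPKM. Immediate early and heat shock genes, which respond to tissue dissociation, were higher in 17 of 18 cases, with a mean difference of 0.28 (SE 0.15, camera adjusted p = 6.36e-05, adjusted p = 0.699 with an estimated correlation) that was 0.19 without atorvastatin library 3. Hspa1b had 1680 ± 183 and 2289 ± 339 FPKM, and Hspa1a had 1523 ± 120 and 2059 ± 308 FPKM. Over 6321 protein-coding genes with a mean of at least 5 FPKM, leaving out ribosomal and mitochondrial ones, the log2 difference rose with transcript length across genes, which are not independent replicates (Spearman's correlation 0.428, and 0.168 without vehicle library 3). Its median was -0.17 for 573 genes under 1000 nt and 0.10 for 1523 genes over 4000 nt.

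**Figure D3:**
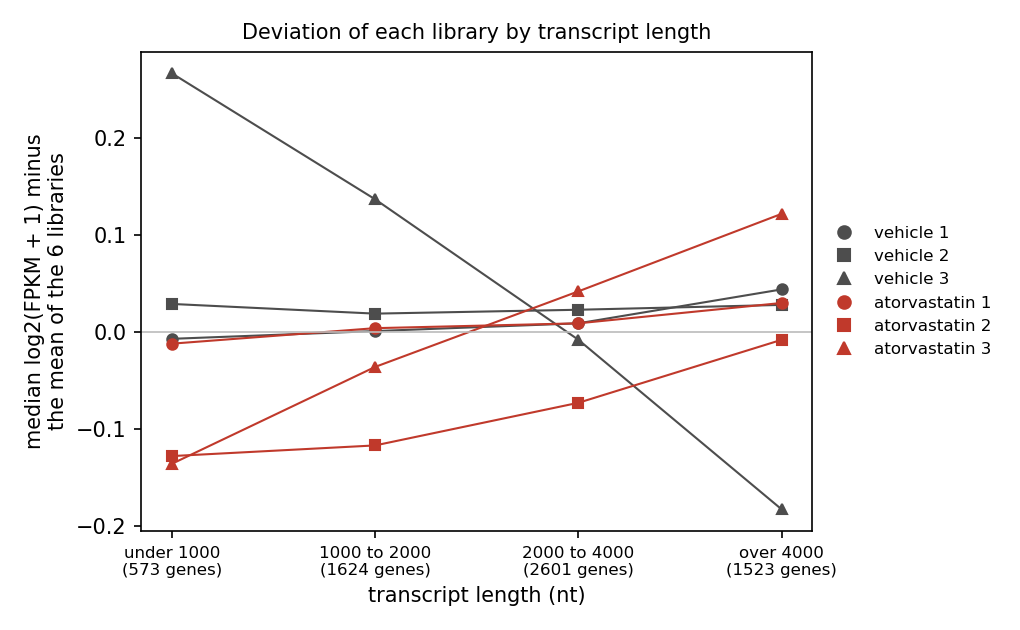
Median deviation of log2(FPKM + 1) of each library from the mean of the 6 libraries, for 6321 protein-coding genes in 4 classes of transcript length (nt). Vehicle library 3 falls from 0.27 in the shortest class to -0.18 in the longest, atorvastatin libraries 2 and 3 go the other way, and the other 3 libraries stay near 0.

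The 10 genes with the smallest p did not pass the threshold (limma adjusted p = 0.291 or 0.518), and 3 of them are gene models named only by a clone or prediction. Coordinates are mm10. Map2k7 (ENSMUSG00000002948, chromosome 8, 4238740 to 4247897), which encodes a kinase that activates JNK, had 1.43 ± 0.282 FPKM (SD, n = 3) with vehicle and 5.57 ± 0.896 with atorvastatin, a log2 difference of 1.43 (SE 0.15). Its model overlaps, on the same strand, the gene model Gm49320 (4238865 to 4251423), another of the 10, named after its value was seen, which had 3.72, 5.78 and 2.13 FPKM with vehicle and is listed at 0 in all 3 atorvastatin libraries. The sum of both was 5.31 ± 2.00 and 5.57 ± 0.896 FPKM. Ccl17 (ENSMUSG00000031780, chromosome 8, 94810453 to 94812036), a chemokine made by dendritic cells, had 13.3 ± 0.413 and 5.14 ± 1.01 FPKM (-1.23, SE 0.15). Emp1 (ENSMUSG00000030208, chromosome 6, 135362545 to 135383173), an epithelial membrane protein, had 113 ± 33.4 and 29.3 ± 5.17 FPKM (-1.89, SE 0.24). Plpp5, a phospholipid phosphatase, had 6.86 ± 0.354 and 3.46 ± 0.575 FPKM. Zhx1, a zinc finger and homeobox protein, had 7.06 ± 0.268 and 4.25 ± 0.163 FPKM. Igkv4-71, a kappa variable segment, had 3.59 ± 0.796 and 0.653 ± 0.431 FPKM, and Zfp469 had 0.537 ± 0.0839 and 1.98 ± 0.440 FPKM. In each of these genes all 3 libraries of a group lay on the same side of the other group.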

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

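No gene passed limma under most settings. With equal sums per library there were 2 genes, 1 higher and 1 lower (Gm15564, Gm49320), and with array weights 4, 1 higher (Map2k7, adjusted p = 0.0481) and 3 lower (Emp1, Ccl17, Gm49320); the cause was not tested. Leaving out single libraries gave 0 to 2 genes, 0 to 1 higher (Gm8210 without atorvastatin library 1) and 0 to 2 lower (Igkv1-99 and Gm26712 without atorvastatin library 3). The number of lists past camera's threshold ran from 8 without vehicle library 1 to 16 without atorvastatin library 2. It was 0 with an estimated correlation and 0 with fry, with 1 and 5 lists at an unadjusted p under 0.05. Among the 10 called lists the estimates ran from 0.105 (Th1) to 0.754 (mitochondrial), against the preset 0.01. They were 0.395 for B cell, 0.199 for MHC class II and 0.48 for ribosomal genes. The preset camera p-values do not allow for correlation of that size and are too small if the estimates hold. The cause of the loss in fry was not tested. With the replicate number as a replicate block there were 0 genes and 10 lists, but libraries sharing a number had r of only -0.109, 0.137 and -0.015 in their deviations from the group means. The mitochondrial list turned to 0.132 (camera adjusted p = 0.228) with length and GC trends removed, both fitted on protein-coding genes alone. The immunoglobulin variable segments ran from -0.159 without atorvastatin library 2 to 0.323 without vehicle library 2. B cell, MHC class II, stress and ribosomal lists held under 15 of 17 alternatives, all but the estimated correlation and fry. Count-based tests, other size factors and voom were not run, since the values are FPKM.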

Other observations

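Immunoglobulin genes, compared after their values were seen, are given here by isotype. Ighm (386, 921 and 286 FPKM with vehicle, 262 ± 21.3 with atorvastatin, SD, n = 3) and Ighd (119 ± 26.2 and 76.4 ± 20.7 FPKM), the heavy chains of naive B cells, were lower without overlap, each with an exact permutation p = 0.1, the smallest possible, and the vehicle mean of Ighm rests on library 2. As a share of heavy constant FPKM, Ighm overlapped between groups (2.54% ± 1.28 and 1.5% ± 0.633, exact permutation p = 0.4). Igha, the heavy chain of gut plasma cells, made up 93.9% ± 1.27 and 95.1% ± 0.423. Ighv1-81 was the most abundant heavy variable segment in 5 of the 6 libraries. The effective number of Ighv segments was 23.4 ± 2.52 and 29.2 ± 3.71 (exact permutation p = 0.1), and that of Igkv segments 26.4 ± 5.07 and 30.5 ± 6.32 (exact permutation p = 0.4). Ighv usage was as similar between groups (mean r = 0.705) as within them (0.708).

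For the B cell and MHC class II lists, rescaling without abundant gene classes was fixed beforehand, while the length test and the comparison with T cells were chosen only after the result was seen. Lower B cell and MHC class II genes could follow from fewer B cells among the cells sequenced, but a shift of the scaling by abundant immunoglobulin RNA is an alternative. Rescaling without immunoglobulin, receptor, ribosomal and mitochondrial genes left the B cell difference at -0.371 (SE 0.115), and removing the length trend left it at -0.37 (SE 0.095) and MHC class II at -0.297 (SE 0.081), so neither explanation accounts for it. A lower share of all lymphocytes is undecided: the T cell list minus the B cell list was 0.364 (SE 0.213, exact permutation p = 0.2). Dendritic cell markers, from other cells with MHC class II, were lower without overlap (-0.13, exact permutation p = 0.1). Germinal centre B cell markers were higher without overlap (0.10, exact permutation p = 0.1). Neither list passed camera (adjusted p = 0.294 and 0.271), and chance alone separates 3 from 3 libraries in 10% of cases. The 2 lists therefore do not show whether fewer B cells would be all of it. Macrophage markers, from cells that also carry MHC class II, went the other way with overlap (0.25, exact permutation p = 0.4). That difference was 0.04 without vehicle library 1.

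The tests that remove the length trend were chosen only after the data were seen. Lower ribosomal and higher stress and smooth muscle genes may reflect RNA quality or library preparation that varies with transcript length. With that trend removed the ribosomal difference went from -0.338 to -0.181 (SE 0.057), so length may carry part of it. Whether length carries the rest is undecided, since the trend was fitted over all protein-coding genes past the filter. Ribosomal genes are shorter (median 795 nt against 2354 nt for all tested genes) and abundant, and the fit may fall short for them. Stress genes stayed at 0.313 (SE 0.123), which length does not explain, while smooth muscle genes went from 0.277 (SE 0.21) to 0.268 (SE 0.228, camera adjusted p = 7.02e-03). That correction barely moved the smooth muscle list, which speaks against length as its whole cause, but the difference itself is under 2 SE before and after, so the explanation is not excluded beyond the spread of the libraries. There are 10 ways to divide the 6 libraries in 3 and 3, and the treatment's own division is counted among them. Of these, 2 gave a length correlation at least as large as the 0.428 of the treatment (highest 0.555). At least as many lists as its 10 came from 6 of them (highest 17). The treatment had 0 genes past the threshold in limma, which no division can go below (highest 3), so that count says nothing on chance. The 10 divisions are too few for a share under 0.05. The division with 17 lists, vehicle libraries 1 and 2 with atorvastatin library 2 against the rest, had 1513 genes at an unadjusted p under 0.05 in limma against 974 for the treatment. It was picked as the division with the most lists, so its counts do not show a structure of the libraries apart from treatment.

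The test of the overlapping gene models was chosen only after the result was seen. Higher Map2k7 may be a matter of how reads were assigned between gene models: the summed FPKM of Map2k7 and Gm49320, on the same strand at the same place, differed by 0.26 (SE 1.26), where Map2k7 alone had 1.43 FPKM with vehicle and 5.57 with atorvastatin. The SE of the sum leaves room for a real change.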
